A study of Mus musculus with 10 samples.

How the data were processed

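Lung RNA of 10 ICR mouse samples was measured on Affymetrix Mouse 430 version 2.0 arrays of 45101 probe sets, with 2 room-air and 3 hyperoxia arrays at each of days 14 and 29. Groups and replicate numbers were taken from the sample titles. The values used were those the authors deposited, on a log2 scale; Partek 6.4 and GCRMA (version not given) are named in the submitters' processing notes, and the settings of the background correction and normalization are not given in the sources used here. Medians per array over all probe sets lay between 6.41 and 6.45 on the hyperoxia arrays and between 6.46 and 6.47 on the room-air arrays. The SD over all probe sets was 2.33 to 2.35 on the hyperoxia arrays and 2.25 to 2.29 on the room-air arrays. Values ranged from 2.51 to 15.00.

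Probe sets were named from the platform annotation given. Of the 45101 probe sets, 34958 had 1 gene symbol, 932 had several and 9211 had none; only those with 1 symbol were used. Entrez gene numbers of 34754 probe sets matched the RefSeq gene table of assembly GRCm38.p6, and 0 symbols changed. Each gene was represented by its probe set of highest mean over the 10 arrays, and of 18194 genes the 14989 with a log2 value of 5 or more on at least 2 arrays were kept. No coordinates are given, because the sources used here name no genome build for the array.

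Group means of all 10 arrays were fitted in 1 linear model with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend or robust fit; 6 residual and 5.09 prior degrees of freedom), which pools the spread over the 4 groups. The 5 contrasts were hyperoxia against room air at P14 and at P29, the difference of these effects, and P29 against P14 in room air and in hyperoxia. Tests were two-sided, and p-values were adjusted by Benjamini-Hochberg over the genes kept, with a threshold of 0.05. Errors given as SE are those of the fitted contrast, and errors given as SD are between arrays of a group. Control probe sets, and the median and 10th percentile of the genes kept, were compared between the 6 hyperoxia and 4 room-air arrays. The test was an exact permutation test over 210 splits, adjusted over these measures. The tests of the pyruvate carboxylase and transferrin receptor controls were added after their values were seen and are not part of that adjustment.

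Before the data were examined, 40 gene lists of pathways, lung cell types and tissues that can come with a dissected lung were fixed. The immediate early and heat shock genes among them were fixed as a technical list, not as a pathway. They held 709 places, of which 626 were measured, 56 had no probe set of 1 gene and 27 lay below the filter. Lists were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and members were also counted with p adjusted over the list alone. At this setting 8 lists were higher and 4 lower at P14, 3 and 7 at P29, 3 and 17 for the difference of effects, 21 and 5 for age in room air, and 14 and 9 for age in hyperoxia. With an estimated correlation 0 and 0, 0 and 1, 0 and 0, 2 and 0, and 1 and 1 lists passed, and at an unadjusted p under 0.05 there were 4 and 1, 1 and 3, 2 and 6, 11 and 2, and 8 and 2. The calls held with an estimated correlation were T and natural killer cell markers at P29, these markers and MHC class II genes for age in room air, and MHC class II and imprinted growth genes for age in hyperoxia. The genes named were also fixed by rule: per hyperoxia comparison the 10 largest rises and 10 largest falls among genes past the threshold whose arrays do not overlap between the groups, 5 and 5 for the other comparisons (without the overlap condition for the difference of effects), and up to 4 members of smallest p of each list described. Other genes named were chosen after their values were seen; these are the comparisons of a named gene with its value in another contrast, and the genes Alas2, Slc4a1 and Dbp where they are set beside another result.

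The steps were tested on simulated data. For the P14 comparison, 100 of 14989 genes were changed by 0.5 on the log2 scale and another 100 by 1. Of these, 63% and 99% were called, with 8 false calls among 170. Where 1 list was shifted, 1 was called. The noise was drawn independently for each gene, so this cannot show how often lists of correlated genes are falsely called. Alternatives fixed beforehand were other filters, other ways to choose or average probe sets, an intensity trend with a robust fit, fits of the compared groups alone, 2 scalings, array weights, a replicate block, leaving out each array, and 2 other list tests. Terms for the actin 3' minus 5' difference and for Y-linked gene level, and the use of the P29 hyperoxia array with female RNA alone, were added after the data were seen. Control probe sets were left out of the gene tests.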

Results

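Lung RNA of newborn ICR mice was measured on 10 expression arrays in a model of bronchopulmonary dysplasia, the chronic lung disease of preterm infants who receive oxygen. Mouse pups breathed 80% oxygen or room air from the first hours after birth until postnatal day 14 (P14) or day 29 (P29). Each age had 3 hyperoxia arrays and 2 room-air arrays. The small number of arrays limits the precision of each value. The labels do not say whether each array came from a separate animal, so the p-values measure only the spread between these samples, which may be technical. P29 hyperoxia replicates 1 and 2 are an exception, because their sex-linked transcripts differed and they cannot be repeats of the same sample. P29 hyperoxia replicate 3 carried both female and male transcripts, so it was not a repeat of either of these alone. Arrays of the same group correlated at r = 0.993 to 0.996 across genes, and arrays of different groups at 0.935 to 0.983. The first principal component held 48.9% of the variance and the second 34.6%.

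Control probe sets and sex-linked transcripts differed between the groups. The 3' minus 5' difference of the actin control, which grows as RNA is degraded or incompletely copied, was 1.75 ± 0.30 (SD, n = 6) on the hyperoxia arrays and 0.53 ± 0.17 (SD, n = 4) on the room-air arrays (exact permutation test, two-sided, p = 0.00476, adjusted over 7 measures 0.00667). The same difference for the Gapdh control was 0.66 ± 0.23 (SD, n = 6) against 0.03 ± 0.12 (SD, n = 4). Of 2 further controls, pyruvate carboxylase was at 2.43 ± 0.37 against 1.68 ± 0.42, with overlapping arrays (exact permutation test, two-sided, p = 0.0238), and the transferrin receptor ran the other way, at 1.76 ± 0.14 against 1.99 ± 0.14 (p = 0.0429). The 18S ribosomal RNA control was 9.09 ± 0.42 (SD, n = 6) against 7.70 ± 0.25 (SD, n = 4), and the hybridisation controls, which are added to the sample, were 10.95 ± 0.08 against 10.18 ± 0.12. Xist, the transcript that silences an X chromosome in females, was low and Y-linked genes were high on all 5 P14 arrays. Both P29 room-air arrays showed the female pattern, with Xist at 12.48 and 12.66. At P29 in hyperoxia, replicate 1 showed the male pattern (Xist at 7.12), replicate 2 the female pattern (12.54), and replicate 3 carried both Xist (11.94) and Y-linked transcripts (mean 7.71).

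**Figure D1:**
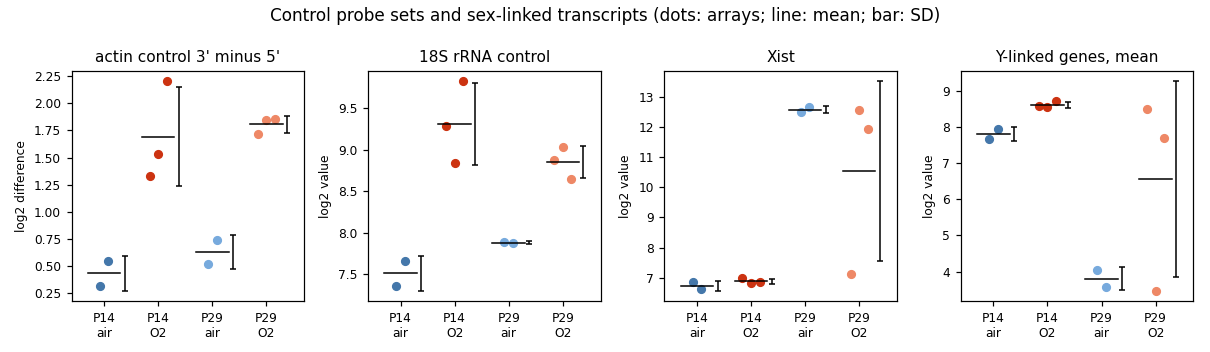
Control and sex-linked signals on each of the 10 arrays, as log2 values or log2 differences, with dots for arrays, lines for group means and bars for the SD. The actin 3' minus 5' difference lies between 1.33 and 2.21 on the hyperoxia arrays and between 0.32 and 0.74 on the room-air arrays.

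The first comparison asked what hyperoxia had changed by P14. Target genes of p53 rose. Cdkn1a, the p53-induced inhibitor of cyclin-dependent kinases, was 5.34-fold higher (11.61 ± 0.15 in hyperoxia against 9.19 ± 0.30 in room air, SD, n = 3 and 2), and the p53 target Eda2r was 12.7-fold higher. Of 21 measured p53 target genes, 18 rose and 0 fell, with a median log2 fold change of 0.66 (camera adjusted p = 7.01e-06, and adjusted p = 0.1985 with an estimated correlation). Of 22 Nrf2 target genes, which encode detoxifying and antioxidant enzymes, 16 rose and 2 fell (adjusted p = 7.47e-05, and adjusted p = 0.35 with an estimated correlation). Nqo1, a quinone reductase, rose by 2.42 ± 0.09 (SE) on the log2 scale and the glutathione transferase Gsta3 by 2.49 ± 0.13. Among the aryl hydrocarbon receptor and cytochrome P450 genes 8 of 11 rose and 1 fell (adjusted p = 0.00869, and adjusted p = 0.433 with an estimated correlation). There Aldh3a1, an aldehyde dehydrogenase, rose by 2.90 ± 0.16 and Aox3, an aldehyde oxidase, by 2.21 ± 0.12, while Cyp1a1 fell by 2.41 ± 0.27. The actin 3' minus 5' difference moved with these groups, at 1.69 ± 0.46 (SD, n = 3) in P14 hyperoxia and 0.43 ± 0.16 (SD, n = 2) in P14 room air.

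Further lists rose at P14. Among hypoxia response genes 14 of 19 rose and 1 fell (adjusted p = 0.000253, and adjusted p = 0.258 with an estimated correlation), with the glucose transporter Slc2a1 up by 2.27 ± 0.12 (SE; 0.56 on another probe set) and Hk2, a hexokinase, up by 1.16 ± 0.11. Of 18 immediate early and heat shock genes 16 rose and 0 fell (adjusted p = 0.000174, and adjusted p = 0.294 with an estimated correlation), among them Hspa1a at 1.73 ± 0.17 and Atf3 at 1.73 ± 0.21. This list was fixed beforehand as a technical one, and whether its rise came from oxygen was not tested. Its median centred log2 value was -0.77 and -0.79 on the P14 room-air arrays, against -0.12 to 0.33 on the others. Ciliated cell markers rose in 13 of 17 cases and fell in 1 (adjusted p = 0.000712, and adjusted p = 0.513 with an estimated correlation), with Ak7 at 1.45 ± 0.11. Complement and coagulation genes rose in 11 of 14 cases and fell in 1 (adjusted p = 0.000712, and adjusted p = 0.1985 with an estimated correlation), with the protein C receptor Procr at 1.69 ± 0.10. Cell cycle genes rose in 18 of 28 cases with a median of 0.47 (adjusted p = 0.00567, and adjusted p = 0.754 with an estimated correlation), led by Ccne2 at 1.28 ± 0.17 and the proliferation marker Mki67 at 0.84 ± 0.13. Without P14 room air replicate 1 the median of the cell cycle list was 0.37 and its adjusted p was 0.0562.

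Neutrophil and lymphocyte markers were lower at P14. Of 15 neutrophil markers 11 fell and 1 rose (adjusted p = 0.000508, and adjusted p = 0.433 with an estimated correlation), with S100a8, a calcium-binding protein abundant in neutrophils, at 9.10 ± 0.11 in hyperoxia and 11.33 ± 0.06 in room air (SD, n = 3 and 2). T and natural killer cell markers fell in 11 of 16 cases and rose in 0 (adjusted p = 0.000712, and adjusted p = 0.1985 with an estimated correlation), with Cd3d at -1.02 ± 0.15 (SE) and Cd3g at -0.84 ± 0.10. B and plasma cell markers fell in 5 of 14 cases and rose in 1 (adjusted p = 0.0149, and adjusted p = 0.589 with an estimated correlation), with the B cell receptor component Cd79a at -1.01 ± 0.15. Without P14 room air replicate 1 that adjusted p was 0.0564. Of 4 red blood cell markers 3 fell, with a median of -0.64, and the list did not pass the test (adjusted p = 0.0712). Among them Alas2, the haem synthesis enzyme of red cell precursors, was at -1.09 ± 0.28, and Slc4a1, the red cell anion exchanger, at -0.18 ± 0.31 (0.64 on another probe set). Elastic fibre and collagen genes fell in 8 of 24 cases and rose in 1, with a median of -0.18 (adjusted p = 0.0208, and adjusted p = 0.637 with an estimated correlation), led by the microfibril proteins Mfap2 at -1.70 ± 0.08 and Emilin1 at -0.96 ± 0.08. Without P14 room air replicate 2 the adjusted p of that list was 0.116. Adjusted over the list alone, the counts of these 12 lists were the same except for 20 risen cell cycle genes, 17 risen immediate early and heat shock genes and 7 fallen elastic fibre and collagen genes.

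In all, 4838 genes were higher and 3411 lower at P14 among 14989 tested with limma at an adjusted p under 0.05, of which 591 and 152 differed by 2-fold or more. The largest rises were Ces1g (4.18 ± 0.11, SE) and Ces1f (3.49 ± 0.15), both carboxylesterases, Muc4, a membrane mucin (4.0 ± 0.26), the neutrophil chemokine Cxcl5 (3.73 ± 0.46), Eda2r (3.67 ± 0.11), the glutathione transferase Gsta2 (3.45 ± 0.11), Col8a1 (3.18 ± 0.13), the endothelial proteoglycan Esm1 (3.0 ± 0.14), the mast cell chymase Cma1 (2.99 ± 0.31) and Ptgs2, the inducible cyclooxygenase (2.96 ± 0.17). The largest falls were Crabp1 (-3.02 ± 0.11), a retinoic acid binding protein, Clca1 (-2.97 ± 0.33), Agt, or angiotensinogen (-2.86 ± 0.21), the airway secretoglobin Scgb3a1 (-2.74 ± 0.20), the macrophage chitinase-like protein Chil3 (-2.54 ± 0.44), Prss35 (-2.43 ± 0.22), Cyp1a1 (-2.41 ± 0.27), Glp1r (-2.30 ± 0.21), the protease inhibitor A2m (-2.25 ± 0.22) and Zfp949 (-2.25 ± 0.09). A second, dimmer probe set of Muc4 gave 0.38, 1 of Ptgs2 gave 0.36, 1 of Col8a1 gave 1.54 and 1 of Zfp949 gave -1.41. Of the calls, 58.6% were higher. This share was 46.8% after quantile normalization and 35.4% once each array was set to its own 75th percentile, which moved the median of all genes from 0.04 to -0.14. With the actin 3' minus 5' difference as a term, an alternative chosen after seeing the data, 809 genes were higher and 578 lower.

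The second comparison asked what hyperoxia had changed by P29. Proliferation genes were far above the room-air level. All 28 measured cell cycle genes rose, with a median log2 fold change of 2.04 (camera adjusted p = 2.28e-14, and adjusted p = 0.427 with an estimated correlation). Mki67 was 7.84-fold higher, at 10.44 ± 0.05 in hyperoxia and 7.47 ± 0.04 in room air (SD, n = 3 and 2), and Top2a, the replication topoisomerase, rose by 2.69 ± 0.15 (SE; 1.32 on another probe set). Of 24 elastic fibre and collagen genes 16 rose and 1 fell (adjusted p = 0.000319, and adjusted p = 0.427 with an estimated correlation), with elastin, Eln, up by 2.43 ± 0.14 (1.35 on another probe set), tenascin C, Tnc, up by 3.38 ± 0.25 and Col5a2 up by 1.45 ± 0.07 (2.11 on another probe set). The p53 target genes rose in 14 of 21 cases and fell in 0, with a median of 0.76 (adjusted p = 1.22e-05, and adjusted p = 0.279 with an estimated correlation). Cdkn1a rose by 2.79 ± 0.13, Eda2r by 4.31 ± 0.11 and Zmat3 by 1.96 ± 0.08. On these arrays the actin 3' minus 5' difference was 1.81 ± 0.08 (SD, n = 3) in hyperoxia and 0.63 ± 0.16 (SD, n = 2) in room air, and the room-air arrays showed the female pattern of sex-linked transcripts while 2 of the 3 hyperoxia arrays carried Y-linked transcripts.

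Endothelial, lymphocyte and neutrophil markers were lower at P29. Of 22 endothelial markers 15 fell and 2 rose (adjusted p = 3.58e-05, and adjusted p = 0.435 with an estimated correlation). Gpihbp1, the capillary anchor of lipoprotein lipase, was 8.75-fold lower, Ramp2 fell by 1.65 ± 0.10 (SE) and Tek, the angiopoietin receptor, by 1.69 ± 0.11, while the lymphatic marker Lyve1 rose by 1.30 ± 0.10. T and natural killer cell markers fell in 14 of 16 cases and rose in 0, with a median of -1.02 (adjusted p = 5.17e-07), a call that held with an estimated correlation (adjusted p = 0.0395). Cd2 was at 4.61 ± 0.12 in hyperoxia and 7.21 ± 0.15 in room air (SD, n = 3 and 2), and granzyme A, Gzma, fell by 2.62 ± 0.17. Of 14 B and plasma cell markers 13 fell, with a median of -1.47 (adjusted p = 7.05e-07, and adjusted p = 0.315 with an estimated correlation), among them Ms4a1 at -2.27 ± 0.15 and the immunoglobulin joining chain Jchain at -3.13 ± 0.19. Neutrophil markers fell in 11 of 15 cases and rose in 1 (adjusted p = 3.58e-05, and adjusted p = 0.427 with an estimated correlation), with S100a8 12.5-fold lower. The red blood cell markers did not pass the list test (adjusted p = 0.705). Alas2 fell by 1.36 ± 0.28, and Slc4a1 differed by 0.00 ± 0.31 (0.63 on another probe set).

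Further lists fell at P29. Alveolar type 2 cell markers fell in 7 of 16 cases and rose in 1 (adjusted p = 0.00671, and adjusted p = 0.818 with an estimated correlation), with surfactant protein B, Sftpb, at -1.74 ± 0.18 (SE) and Napsa, which processes it, at -1.32 ± 0.14. Of 6 fat cell markers 5 fell and 1 rose (adjusted p = 0.00671, and adjusted p = 0.427 with an estimated correlation), led by adiponectin, Adipoq, at -2.91 ± 0.24 and Fabp4 at -1.87 ± 0.13. MHC class II and dendritic cell genes fell in 7 of 12 cases and rose in 1 (adjusted p = 0.027, and adjusted p = 0.315 with an estimated correlation), with Ccr7 at -1.60 ± 0.14 and H2-Aa at -0.71 ± 0.12, against a rise of Itgae by 1.62 ± 0.21. The fall of H2-Aa rests on 1 of its 3 probe sets, as the others gave -0.07 and 0.29. The MHC class II call ended without P29 room air replicate 2 (adjusted p = 0.0571). Adjusted over the list alone, the counts of the 10 lists called at P29 were the same.

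At P29, 5119 genes were higher and 3829 lower, of which 746 and 356 differed by 2-fold or more. The largest rises were Psrc1, a spindle protein and p53 target (4.80 ± 0.20, SE), the acute-phase protein Saa3 (4.45 ± 0.16), Eda2r (4.31 ± 0.11), the endopeptidase Phex (3.68 ± 0.12), Tmem255a (3.49 ± 0.14), Zfp979 (3.42 ± 0.66), the actin-bundling protein Fscn1 (3.41 ± 0.19), cyclin E2, Ccne2 (3.39 ± 0.17), Tnc (3.38 ± 0.25) and Clca1 (3.31 ± 0.33). Another probe set of Psrc1 gave 1.33 and 1 of Tmem255a gave 0.51, and the 3 other probe sets of Fscn1 gave -0.25, -0.07 and -0.05. The largest falls were the airway protein Bpifa1 (-3.86 ± 0.52), Igkv8-30, an immunoglobulin light chain segment (-3.83 ± 0.25), the eosinophil-associated ribonuclease Ear3 (-3.78 ± 0.29), Gdpd3 (-3.74 ± 0.27), S100a8 (-3.65 ± 0.16), Fabp1 (-3.60 ± 0.24), S100a9 (-3.40 ± 0.13), the receptor tyrosine kinase Kit (-3.36 ± 0.17), Nrn1 (-3.34 ± 0.12) and Cytl1 (-3.30 ± 0.14). Of the calls, 57.2% were higher, and 37.3% once each array was set to its own 75th percentile, which moved the median of all genes from 0.04 to -0.13. With the actin 3' minus 5' difference as a term, 1628 genes were higher and 1277 lower. The adjusted p of the alveolar type 2 list became 0.0669 and that of the MHC class II list 0.151.

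**Figure D2:**
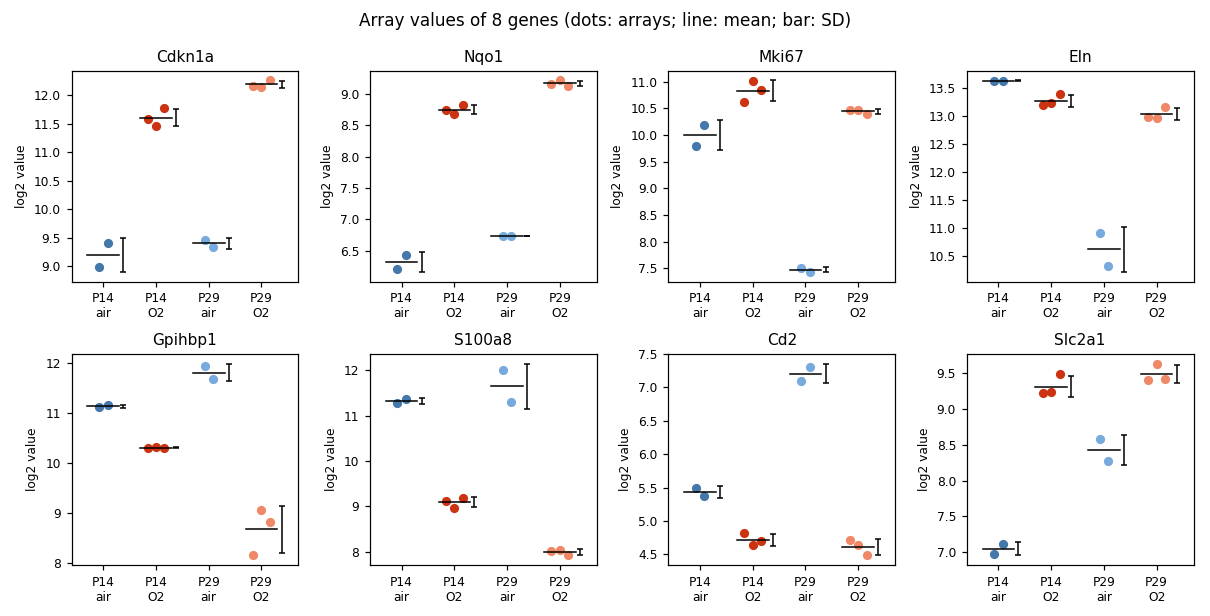
Log2 values of 8 genes on each array, with dots for arrays, lines for group means and bars for the SD. Mki67 is at 7.47 in P29 room air and at 10.44 in P29 hyperoxia, and Cdkn1a is above 11 on each hyperoxia array and below 10 on each room-air array.

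The hyperoxia effects at the 2 ages, which share no array, were set against each other. Across genes the log2 fold changes correlated at r = 0.608 (Spearman rho 0.673); genes are not independent replicates. Higher at both ages were 3339 genes, against 1652 for independent lists of that length, and lower at both were 2127, against 871. Opposite calls were made for 397 genes. The actin, Gapdh, ribosomal RNA and hybridisation controls separated the hyperoxia arrays from the room-air arrays at both ages. A shift common to the hyperoxia arrays would also give such a correlation and overlap. These values therefore cannot tell it from a response to oxygen. Nqo1 changed alike, at 2.42 ± 0.09 (SE) and 2.43 ± 0.09. The effects on Cdkn1a differed by 0.38 ± 0.18 (limma adjusted p = 0.16).

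The test of the difference between the effects asked which genes responded otherwise at P29 than at P14. Cell cycle genes had the smallest p. All 28 had a higher effect at P29, with a median difference of 1.64 (camera adjusted p = 9.56e-22, and adjusted p = 0.231 with an estimated correlation), and Cdk1 differed by 2.19 ± 0.21 (SE). Of 24 elastic fibre and collagen genes 19 had a higher effect at P29 and 0 a lower one (adjusted p = 1.22e-14, and adjusted p = 0.149 with an estimated correlation), with Eln at 2.78 ± 0.20, Tnc at 4.04 ± 0.36 and Col5a2 at 1.32 ± 0.10. Imprinted growth genes differed upwards in 6 of 15 cases and downwards in 0 (adjusted p = 0.0113, and adjusted p = 0.24 with an estimated correlation), with Grb10, an inhibitor of growth factor signalling, at 1.45 ± 0.11 and Peg3 at 1.11 ± 0.13 (0.90 and 0.51 on other probe sets). Effects were lower at P29 for 8 of 11 aryl hydrocarbon receptor and cytochrome P450 genes and higher for 1 (adjusted p = 8.9e-07, and adjusted p = 0.213 with an estimated correlation), with the flavin monooxygenase Fmo1 at -2.09 ± 0.17. They were also lower for 11 of 22 Nrf2 targets and higher for 2 (adjusted p = 0.000107, and adjusted p = 0.24 with an estimated correlation). The same held for 13 of 22 endothelial markers, with 1 higher (adjusted p = 1.6e-06, and adjusted p = 0.24 with an estimated correlation), and for 9 of 14 club cell markers, with 1 higher (adjusted p = 3.58e-05, and adjusted p = 0.231 with an estimated correlation). Examples are Gsta3 at -2.67 ± 0.19, the caveolar protein Plvap at -1.93 ± 0.14 and the club cell cytochrome Cyp2f2 at -1.26 ± 0.10. Markers of other tissues moved the same way. Fat cell markers had a median difference of -1.35 (camera adjusted p = 0.000275, and adjusted p = 0.231 with an estimated correlation). Cardiac muscle and mesothelial cell markers were also past the test at the preset correlation, with lower effects at P29.

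For the difference of effects, 1642 genes were higher and 1735 lower. The largest positive differences were Clca1 (6.28 ± 0.46, SE), which fell at P14 and rose at P29, Tnc (4.04 ± 0.36), the chemokine Ccl12 (3.46 ± 0.33), Phex (3.42 ± 0.18) and Saa3 (3.13 ± 0.22). The largest negative ones were Muc4 (-4.79 ± 0.36), Ear3 (-4.63 ± 0.41), Bpifa1 (-4.07 ± 0.73), the growth factor carrier Igfbp3 (-3.86 ± 0.22) and Esm1 (-3.52 ± 0.20). The Muc4 difference turned to 0.18 (adjusted p = 0.426) with the probe set used when those with ambiguous suffixes were left out. With the P29 hyperoxia array of female pattern as the lone P29 hyperoxia array, an alternative chosen after seeing the data, 1029 genes were higher and 1059 lower. Adjusted over the list alone, the counts of the lists given here rose to 20 of the elastic fibre and collagen genes, 10 lower P450 genes, 12 lower Nrf2 targets and 14 lower endothelial markers, and were otherwise the same.

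**Figure D3:**
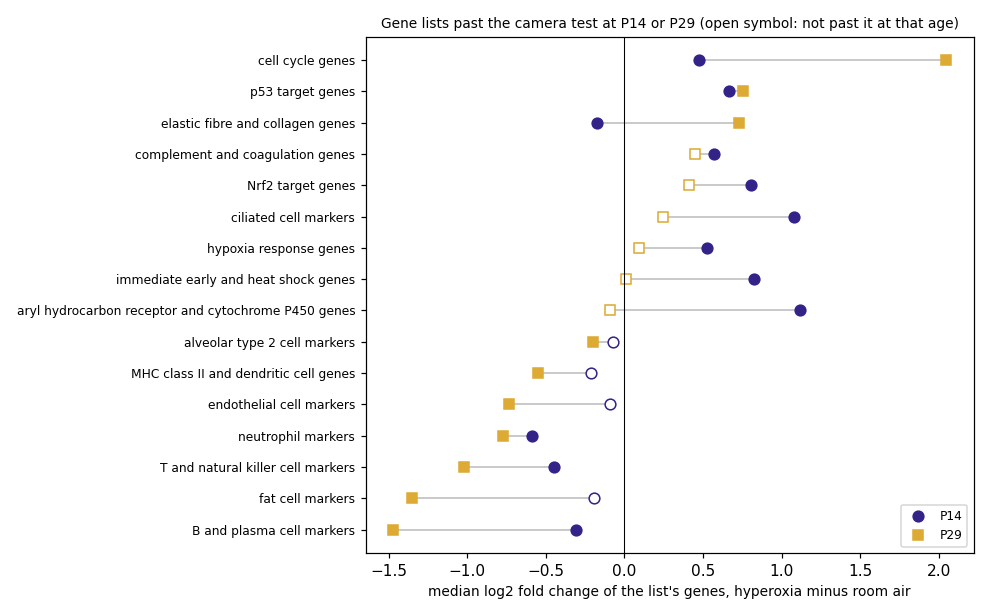
Median log2 fold change between hyperoxia and room air of the gene lists past the camera test with preset correlation at P14 (circles) or P29 (squares), with open symbols where the list did not pass at that age. The cell cycle median is 0.47 at P14 and 2.04 at P29, and the elastic fibre and collagen median is -0.18 at P14 and 0.73 at P29.

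The comparison of P29 with P14 in room air described the change with age without added oxygen. All 28 cell cycle genes fell, with a median of -2.04 (camera adjusted p = 1.69e-19, and adjusted p = 0.155 with an estimated correlation). Mki67 was 5.75-fold lower at P29. Of 24 elastic fibre and collagen genes 21 fell and 0 rose (adjusted p = 7.08e-15, and adjusted p = 0.0657 with an estimated correlation), with Eln 8.11-fold lower, at 10.61 ± 0.41 against 13.63 ± 0.01 (SD, n = 2 and 2). Imprinted growth genes fell in 12 of 15 cases (adjusted p = 8.35e-07, and adjusted p = 0.0657 with an estimated correlation), with Peg3 at -2.70 ± 0.10 (SE) and Igf2, a fetal growth factor, at -1.22 ± 0.10. Club cell markers rose in 13 of 14 cases (adjusted p = 2.15e-09, and adjusted p = 0.0657 with an estimated correlation) and ciliated cell markers in 16 of 17 (adjusted p = 4.07e-08, and adjusted p = 0.151 with an estimated correlation), with Cyp2f2 at 1.60 ± 0.08 and Ak7 at 1.65 ± 0.12. Of 11 aryl hydrocarbon receptor and cytochrome P450 genes 10 rose (adjusted p = 7.42e-08, and adjusted p = 0.082 with an estimated correlation), with Cyp2b10 at 4.96 ± 0.26.

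Immune cell markers rose with age in room air. T and natural killer cell markers rose in 12 of 16 cases (adjusted p = 3.6e-06) and MHC class II and dendritic cell genes in 10 of 12 (adjusted p = 7.28e-06), and both calls held with an estimated correlation (adjusted p = 0.0486 for each). Cd3g rose by 2.03 ± 0.11 (SE) and the MHC class II chain H2-Ab1 by 1.72 ± 0.11. B and plasma cell markers rose in 12 of 14 cases (adjusted p = 6.94e-06, and adjusted p = 0.151 with an estimated correlation), with Jchain at 3.90 ± 0.21. Interferon response genes rose in 15 of 19 and fell in 2 (adjusted p = 7.21e-06, and adjusted p = 0.161 with an estimated correlation), with Gbp2 at 2.06 ± 0.11. On the same arrays markers of other tissues moved as well. All 6 fat cell markers rose (adjusted p = 0.000157, and adjusted p = 0.151 with an estimated correlation), cardiac muscle markers rose in 8 of 14 cases and fell in 1 (adjusted p = 0.00957, and adjusted p = 0.428 with an estimated correlation), and 3 of 4 red blood cell markers fell (adjusted p = 0.0136, and adjusted p = 0.186 with an estimated correlation). Across the genes tested 3329 were higher and 2866 lower. Among the 5 largest changes in each direction were sex-linked transcripts. Both P14 arrays showed the male and both P29 arrays the female pattern. Xist rose by 5.83 ± 1.27 (7.30 and 1.68 on other probe sets), and the Y-linked Eif2s3y (-5.23 ± 1.41) and Kdm5d (-4.26 ± 1.21, with -1.10 on a dimmer probe set) fell. The others were Bpifa1 (7.34 ± 0.57), Ms4a4d (5.04 ± 0.12), Cyp2b10 and Ear3 (4.73 ± 0.32) among the rises, and Prss35 (-4.43 ± 0.24), Tnc (-4.34 ± 0.28) and Phex (-3.81 ± 0.14) among the falls. With the level of Y-linked genes as a term, chosen after seeing the data, 2163 genes were higher and 1832 lower.

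The comparison of P29 with P14 in hyperoxia described the change with age under oxygen. MHC class II and dendritic cell genes rose in 12 of 12 cases, with a median of 0.93 (camera adjusted p = 4.46e-09), and imprinted growth genes fell in 11 of 15 cases, with a median of -0.66 (adjusted p = 4.46e-09). Both calls held with an estimated correlation (adjusted p = 0.0237 and 0.0437). H2-Ab1 rose by 1.36 ± 0.09 (SE) and the invariant chain Cd74 by 1.12 ± 0.11, and Peg3 fell by 1.58 ± 0.08. Macrophage markers rose in 15 of 19 cases (adjusted p = 4.46e-09, and adjusted p = 0.126 with an estimated correlation), with the complement component C1qb at 1.14 ± 0.10 and the elastase Mmp12 at 1.42 ± 0.16. Interferon response genes rose in 16 of 19 cases and fell in 1 (adjusted p = 4.46e-09, and adjusted p = 0.156 with an estimated correlation), with Ifit1 at 1.99 ± 0.19. Cell cycle genes fell in 18 of 28 cases and rose in 2, with a median of -0.48 (adjusted p = 2.75e-05, and adjusted p = 0.436 with an estimated correlation). The list test fry, which does not compare a list with other genes, gave an adjusted p of 0.0546. On the same arrays 3 of 4 red blood cell markers fell, with a median of -0.98 (adjusted p = 0.00923, and adjusted p = 0.222 with an estimated correlation), and 5 of 9 mesothelial cell markers fell, with a median of -0.46 (adjusted p = 0.0065, and adjusted p = 0.37 with an estimated correlation).

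Structural and endothelial genes fell with age in hyperoxia. Elastic fibre and collagen genes fell in 12 of 24 cases and rose in 2, with a median of -0.30 (adjusted p = 1.55e-06, and adjusted p = 0.184 with an estimated correlation). The fetal fibrillin Fbn2 fell by 2.98 ± 0.17 (SE) and Col1a1 by 0.91 ± 0.10, while Mfap5 rose by 1.30 ± 0.12. Of 22 endothelial markers 11 fell and 2 rose (adjusted p = 9.95e-05, and adjusted p = 0.312 with an estimated correlation), with the transcription factor Sox17 at -2.18 ± 0.09 and Aplnr at -1.57 ± 0.13. Club cell markers rose in 12 of 14 cases (adjusted p = 3.9e-08, and adjusted p = 0.126 with an estimated correlation), led by Scgb3a1 at 3.81 ± 0.18. Under hyperoxia 2315 genes were higher and 1748 lower. The other large rises were Cyp1a1 (3.74 ± 0.24), Xist (3.65 ± 1.03), Saa3 (3.49 ± 0.14) and the carbonic anhydrase Car3 (3.31 ± 0.30, with 0.66 on a dimmer probe set). The rise of Xist follows the sex pattern of the arrays. It was at 6.82 to 6.99 on the P14 hyperoxia arrays and at 7.12, 12.54 and 11.94 on those of P29. The other large falls were the hypoxia-induced Ankrd37 (-2.49 ± 0.09), the Wnt inhibitor Wif1 (-2.29 ± 0.11) and Prss35 (-2.15 ± 0.20). Adjusted over the list alone, counts in the age comparisons rose by at most 2 for the lists given here.

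The change with age was set against itself across exposures, which share no array. The log2 fold changes in room air and in hyperoxia correlated across genes at r = 0.582 (Spearman rho 0.517), with a slope of hyperoxia on room air of 0.337. The same genes rose with age in both exposures in 1426 cases, against 514 for independent lists, and fell in both in 1004, against 334. In both exposures the P14 arrays showed the male pattern, while P29 arrays were female in room air and mixed in hyperoxia. How much of the agreement comes from this was not tested. Fbn2 fell alike, by 3.24 ± 0.21 (SE) and 2.98 ± 0.17, as did the clock output gene Dbp in the other direction, at 2.69 ± 0.27 and 2.75 ± 0.22. Eln, by contrast, fell by 3.02 ± 0.16 in room air, and its value in hyperoxia was -0.24 ± 0.13 (limma adjusted p = 0.2).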

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

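The tests with a term for the actin 3' minus 5' difference or for Y-linked gene level, those of a shift common to the hyperoxia arrays, and those of the pyruvate carboxylase and transferrin receptor controls were chosen after the result was seen, while the test on matched random lists and the bound for red blood cell markers were not. The reading that set this bound aside was made after its members were seen.

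The p53 target genes were higher in hyperoxia at both ages, with medians of 0.66 at P14 and 0.76 at P29, on arrays whose RNA controls also differed from room air. With the actin term the smaller of the 2 medians was 0.67 (P14) and the P29 median was 1.01, both past the list test fry. The median SE rose from 0.11 to 0.23 at P14, and members past the test went from 18 to 7 there. The actin values do not overlap between hyperoxia (1.33 to 2.21) and room air (0.32 to 0.74). The term thus rests on differences within groups, extended over a gap that no group spans. It cannot decide whether 3' bias, as the actin control measures it, was the cause. Of 10000 random lists matched on mean level, 0% had a median as high at either age (highest 0.55 and 0.63), a larger shift than for unrelated genes. The random lists were not matched on spread or on correlation between members, and the p53 call ended at both ages with an estimated correlation. They therefore cannot decide on the wider spread of values on the hyperoxia arrays. The SD over all probe sets was 2.33 to 2.35 on those arrays, against 2.25 to 2.29 on the room-air arrays. A shift from 1 processing batch shared by the hyperoxia arrays cannot be told apart, since the actin, Gapdh, 18S and hybridisation controls separate the hyperoxia arrays from the room-air arrays, and the median difference between the ages was 0.28 (camera adjusted p = 0.0512). The response to oxygen itself stays open as untested.

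Cell cycle genes stood out because their hyperoxia effect differed between the ages, at 0.47 for P14 and 2.04 for P29. With the actin term the P29 median was 1.89, with 26 of 28 members past the test and the list past fry. As for the p53 list, this term cannot decide on 3' bias, because the actin values do not overlap between the exposures. With the Y-linked gene level as a term the P29 median was 2.04, with the 28 members past the test and the list past fry. That term rests mostly on P29 hyperoxia replicate 2, the lone P29 hyperoxia array low in Y-linked transcripts, so it cannot decide on female RNA. The median centred log2 value of the list was 0.37 on that array, against -1.51 and -1.93 on the P29 room-air arrays, which share its female pattern. A shift from 1 batch shared by the hyperoxia arrays would be alike at both ages, and the difference of 1.64 (camera adjusted p = 9.56e-22) argues against it as the whole cause, but a batch for each group of arrays is confounded with the groups. Oxygen exposure and age stay open as untested.

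T and natural killer cell markers stood out for the same reason, with medians of -0.45 at P14 and -1.02 at P29. With the actin term the P29 median was -0.78, with 7 of 16 members past the test instead of 14. With the Y-linked gene level it was -0.95, with 13 past it, and the list was past fry in both fits. For the reasons given for the lists above, neither term can decide on 3' bias, as that control measures it, or on female RNA. On P29 hyperoxia replicate 2, of female pattern, the median centred log2 value of the list was -0.15, against 0.86 and 0.89 on the P29 room-air arrays. Less blood in the hyperoxia lungs cannot be told apart, with a median of the 4 red blood cell markers of -0.12 at P29. The bound set beforehand was met, a gap of 0.90 to the T and natural killer cell median against an SD of 0.72. It was set aside after the members were seen, because they disagree. Alas2 fell by 1.36, while Slc4a1 was at 0.00 and at 0.63 on another probe set, which goes against less blood. Epb42 lies near the floor and Car2 is also made by lung cells. Fat cell markers, of a tissue that can come with a dissected lung, also fell at P29, with a list median of -1.35. Thymus markers had centred medians of 0.22 and 0.25 in P29 room air against -0.15 to -0.03 in P29 hyperoxia. The thymus, cardiac, skeletal muscle and mesothelial lists were not past the test there. Whether tissue dissected with the lung contributed was not tested. Fewer lymphocytes in the lung after oxygen stay open as untested.

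Among the lists past the test at P14 or at P29, 11 others were also past the test of the difference between the effects, with median differences of -0.41 for Nrf2 targets, -1.56 for aryl hydrocarbon receptor and cytochrome P450 genes, -0.62 for ciliated cell, -0.59 for endothelial, -0.33 for neutrophil, -0.75 for B and plasma cell and -1.35 for fat cell markers, 0.84 for elastic fibre and collagen genes, -0.53 for hypoxia response, -0.91 for immediate early and heat shock and -0.16 for complement and coagulation genes. The adjusted p values of that test for these 11 lists, cell cycle genes and T and natural killer cell markers were between 0.115 and 0.481 with an estimated correlation. The complement and coagulation call ended without P14 room air replicate 2 (camera adjusted p = 0.0817), P14 hyperoxia replicate 1 (0.0542), P29 room air replicate 1 (0.134) or P29 hyperoxia replicate 1 (0.0633), and its median was 0.03 with probe sets of ambiguous suffix left out. The neutrophil call ended without the same arrays (camera adjusted p = 0.0936, 0.0519, 0.189 and 0.0528) or P29 hyperoxia replicate 2 (0.0767), and its median was -0.16 (0.212) with those probe sets left out.

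The same test of the difference was past the threshold for 34 of the 38 genes named as largest changes at P14 or P29. Positive differences were A2m 2.98, Agt 2.48, Ccne2 2.12, Clca1 6.28, Crabp1 2.65, Cyp1a1 2.69, Eda2r 0.64, Fscn1 2.74, Phex 3.42, Prss35 2.28, Psrc1 2.97, Saa3 3.13, Scgb3a1 1.24, Tmem255a 2.71, Tnc 4.04, Zfp949 0.49 and Zfp979 2.86. Negative differences were Bpifa1 -4.07, Ces1f -2.01, Ces1g -2.01, Col8a1 -1.67, Cytl1 -3.25, Ear3 -4.63, Esm1 -3.52, Fabp1 -2.07, Gdpd3 -2.62, Gsta2 -1.62, Igkv8-30 -2.72, Kit -1.70, Muc4 -4.79, Nrn1 -2.76, Ptgs2 -1.61, S100a8 -1.42 and S100a9 -1.56. Other probe sets gave smaller differences for Psrc1 (0.999), Tmem255a (0.45), Fscn1 (1.24, 0.78 and 0.55), Zfp949 (0.02), Col8a1 (-1.06), Kit (-0.80) and Ptgs2 (-0.78), and for Muc4 0.18, against alike or larger ones for Tnc (4.13) and Fabp1 (-2.83).

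Several control probe sets outside the gene tests were higher on the 6 hyperoxia arrays than on the 4 room-air arrays. The differences were 1.22 for the actin 3' minus 5' value, 0.63 for that of Gapdh, 1.39 for 18S ribosomal RNA and 0.77 for the hybridisation controls (exact permutation test, two-sided, p = 0.00476 each), and 0.65 for the poly-A controls (p = 0.019). The 3' minus 5' values of 2 further controls did not move together, at 0.75 for pyruvate carboxylase and -0.23 for the transferrin receptor (exact permutation test, two-sided, p = 0.0238 and 0.0429), so the actin term stands for only some of the control ratios.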

How the results depend on the processing

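The alternatives with a term for the actin 3' minus 5' difference or for Y-linked gene level, and with the P29 hyperoxia array of female pattern alone, were chosen after seeing the data, and the others before. Unless a reason is given, the cause was not tested. The number of arrays limits precision, and where leaving out an array left 1 in a group, that lone sample was assumed to vary like the other groups. Of 419 results for named genes, 415 or more kept their direction and their side of the threshold with an intensity trend and robust fit, array weights, a replicate block, quantile normalization, the 75th percentile scaling and no filter. With the actin term 22 lost their call, and with the Y-linked term 10. The named genes were chosen for large changes or small p, so these numbers do not stand for all genes. The correlation of the hyperoxia effects at the 2 ages lay between 0.550 and 0.636 when arrays were left out in turn. The Muc4 difference of effects turned to 0.18 when probe sets with ambiguous suffixes were left out, because another probe set then stood for the gene.

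Counts of genes that moved by more than 1.5 times were as follows. With a filter at log2 7, which tests fewer genes, 2471 were lower at P29. With each probe set on its own, which tests more, 7693 were higher and 6792 lower at P14, 8268 and 7324 at P29, 4565 lower with age in room air and 2796 lower with age in hyperoxia. With the 75th percentile scaling 3212 were higher and 5867 lower at P14, and 5950 lower at P29. With the actin term 809 were higher and 578 lower at P14, and 1628 and 1277 at P29. With the Y-linked term 2163 were higher and 1832 lower with age in room air. With the P29 hyperoxia array of female pattern alone 1029 were higher and 1059 lower for the difference of effects, with fewer arrays.

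Counts of lists past the test moved as well. With the log2 7 filter 7 lists were lower at P14, and with the mean of the probe sets of a gene 2. With fry 17 were higher and 9 lower at P14, 13 and 12 at P29, and 8 lower with age in room air. With an estimated correlation camera called 0 higher and 0 lower at P14, 0 and 1 at P29, 0 and 0 for the difference of effects, 2 and 0 with age in room air, and 1 and 1 with age in hyperoxia. Lists higher for the difference of effects numbered 3 to 5 when arrays were left out in turn, with 5 without P29 room air replicate 1.

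With an estimated correlation 86 of the 91 list calls ended, which leaves each median as it was because the test alone changes. At P14 these were p53 0.66, Nrf2 0.80, P450 1.11, cell cycle 0.47, ciliated cell 1.08, elastic fibre and collagen -0.18, neutrophil -0.59, T and natural killer cell -0.45, B cell -0.31, hypoxia 0.53, immediate early 0.83 and complement 0.57. At P29 they were p53 0.76, cell cycle 2.04, alveolar type 2 -0.20, endothelial -0.74, elastic fibre and collagen 0.73, neutrophil -0.77, B cell -1.47, MHC class II -0.55 and fat cell -1.35. For the difference of effects they were Nrf2 -0.41, P450 -1.56, cell cycle 1.64, alveolar type 1 -0.25, transitional epithelium -0.34, club cell -0.80, ciliated cell -0.62, endothelial -0.59, elastic fibre and collagen 0.84, neutrophil -0.33, T and natural killer cell -0.62, B cell -0.75, angiogenic -0.30, hypoxia -0.53, immediate early -0.91, imprinted 0.38, complement -0.16, cardiac -1.29, fat cell -1.35 and mesothelial -0.48. With age in room air they were Nrf2 0.48, P450 2.04, cell cycle -2.04, alveolar type 2 0.40, alveolar type 1 0.39, transitional epithelium 0.53, club cell 1.59, ciliated cell 0.99, elastic fibre and collagen -1.22, macrophage 0.51, neutrophil 0.48, cytokine 0.26, interferon 0.69, B cell 0.86, hypoxia 0.40, sterol and fatty acid 0.51, clock 0.63, immediate early 0.89, imprinted -0.66, complement 0.86, oxidative phosphorylation -0.17, cardiac 0.77, red blood cell -1.38 and fat cell 1.41. With age in hyperoxia they were p53 0.37, Nrf2 0.26, P450 0.58, cell cycle -0.48, alveolar type 2 0.11, club cell 0.46, ciliated cell 0.37, endothelial -0.29, elastic fibre and collagen -0.30, smooth muscle -0.35, macrophage 0.74, cytokine 0.46, interferon 0.71, T and natural killer cell 0.17, mast cell -0.47, TGF-beta -0.062, sterol and fatty acid 0.39, clock 0.70, ER stress 0.38, red blood cell -0.98 and mesothelial -0.46.

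Other settings ended fewer list calls. For the difference of effects, complement had medians of -0.15 (log2 7 filter), 0.0300 (ambiguous suffixes left out, where median and test differ in sign), -0.21 (Y-linked term) and -0.25 (female pattern alone), neutrophil -0.16 (ambiguous suffixes), -0.32 (quantile) and -0.26 (array weights), and alveolar type 1 -0.22 (quantile) and -0.24 (array weights). At P14, elastic fibre and collagen was at -0.12 (mean of probe sets) and B cell at -0.34 (mean of probe sets, and quantile). At P29, MHC class II was at -0.33 (mean of probe sets), -0.60 (ambiguous suffixes), -0.72 (75th percentile), -0.62 (quantile) and -0.62 (actin term), and alveolar type 2 at -0.27 (actin term). With age in room air, hypoxia was at 0.22 (mean of probe sets), 0.37 (ambiguous suffixes) and 0.40 (only the groups compared), neutrophil at 0.48 (ambiguous suffixes), cytokine at 0.22 (actin term) and oxidative phosphorylation at -0.17 (log2 7 filter, and Y-linked term). With age in hyperoxia, TGF-beta was at -0.0579 (log2 7 filter), -0.062 (only the groups compared), -0.0588 (quantile), -0.0673 (mean of probe sets), -0.0678 (75th percentile), -0.0689 (actin term) and -0.0439 (array weights), clock at 0.66 (mean of probe sets), mast cell at -0.32 (array weights), -0.47 (fry), -0.45 (actin term) and -0.36 (Y-linked term), and cell cycle at -0.48 (fry).

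With the replicate number as a block, calls for neutrophil (-0.33) and complement (-0.16) for the difference of effects and for TGF-beta with age in hyperoxia (-0.062) ended. Residuals of same-numbered arrays correlated at -0.099 to 0.197, over 0.1 in 2 of 13 pairs. The residuals of the 2 arrays of a room-air group mirror each other, so these pairs are not independent. They cannot decide whether the numbers pair the arrays. The blocked counts were 4645 higher and 3387 lower at P14, 4935 and 3846 at P29, 1577 and 1675 for the difference of effects, 3269 and 2841 with age in room air, and 2241 and 1706 with age in hyperoxia.

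Leaving out 1 array ended list calls in these cases, with the range of medians over the arrays left out. At P14 these were cell cycle (0.37 to 0.56) and B cell (-0.38 to -0.20), both without room air replicate 1, and elastic fibre and collagen (-0.22 to -0.10) without room air replicate 2. At P29 it was MHC class II (-0.58 to -0.45) without room air replicate 2. For the difference of effects they were alveolar type 1 (-0.33 to -0.18) without P14 hyperoxia replicate 1, P29 room air replicate 2 or P29 hyperoxia replicate 2, angiogenic (-0.32 to -0.19) without P14 room air replicate 1 or P29 room air replicate 2, complement (-0.27 to -0.0830) without P14 room air replicate 2, P14 hyperoxia replicate 1, P29 room air replicate 1 or P29 hyperoxia replicate 1, and neutrophil (-0.48 to -0.22) without any of these 4 or P29 hyperoxia replicate 2. With age in room air they were cytokine (0.16 to 0.27) without P14 room air replicate 2, P14 hyperoxia replicate 3 or P29 room air replicate 1, hypoxia (0.29 to 0.51) without P14 room air replicate 1, oxidative phosphorylation (-0.22 to -0.0748) without P29 room air replicate 2, and neutrophil (0.39 to 0.67) without P14 room air replicate 2 or P29 room air replicate 1. With age in hyperoxia they were alveolar type 2 (0.0495 to 0.21) without P14 hyperoxia replicate 2 or P29 hyperoxia replicate 1, mast cell (-0.77 to -0.17) without P14 hyperoxia replicate 1 or P29 hyperoxia replicate 2, and TGF-beta (-0.12 to -0.0591) without any room-air array, P14 hyperoxia replicate 1 or P29 hyperoxia replicate 1.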

Other observations

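Tests of the covariance with the age change in this part were chosen after the result was seen, and the count over splits of the hyperoxia arrays was not.

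Some clock genes differed between exposures, although the list was not past the test at either age. Cry1, a repressor of the clock, rose in hyperoxia by 1.10 ± 0.10 (SE) at P14 and 1.45 ± 0.10 at P29, while Nr1d1 fell by 1.69 ± 0.15 at P29. The brightest probe set of Per2 gave 1.18 ± 0.09 and 1.06 ± 0.09, but 2 others gave -0.49 and 0.27 at P14 and -0.23 and 0.35 at P29. At P14 7 of 16 clock genes rose and 5 fell, and at P29 5 rose and 4 fell, also 5 and 3 adjusted over the list alone (camera adjusted p = 0.344 and 0.928). With age, where the list was past the test, 9 rose and 3 fell in room air (adjusted p = 0.0133, and adjusted p = 0.138 with an estimated correlation), with Nr1d1 at 2.68 ± 0.17, and 9 rose and 3 fell in hyperoxia (adjusted p = 0.0181, and adjusted p = 0.156 with an estimated correlation), with Nfil3 at -1.79 ± 0.15.

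Single genes of other lists not past the test differed between exposures. The mast cell protease Cma1 rose by 2.99 ± 0.31 (SE) at P14 and 2.36 ± 0.31 at P29, and carboxypeptidase A3, Cpa3, by 2.22 ± 0.25 at P14, while Kit, which mast cells share with capillary endothelium, was at -1.67 ± 0.17 and -3.36 ± 0.17. The mast cell list was not past the test at P14 (camera adjusted p = 0.17). Fdps, a sterol synthesis enzyme, was at -1.22 ± 0.10 and -1.20 ± 0.10, in a list not past the test at either age (adjusted p = 0.586 and 0.106). Markers of tissues next to the lung differed as well: the mesothelial Muc16 rose by 1.92 ± 0.16 and the cardiac troponin Tnnt2 by 1.02 ± 0.17 at P14, and at P29 atrial Nppa rose by 2.38 ± 0.41 while Pln was at -1.26 ± 0.20 and Sln at -1.91 ± 0.32. The difference of effects was past the test for cardiac markers (8 of 14 lower, 1 higher, median -1.29, adjusted p = 0.000467, and adjusted p = 0.386 with an estimated correlation) and for mesothelial markers (4 of 9 lower, adjusted p = 0.000467, and adjusted p = 0.268 with an estimated correlation).

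The hyperoxia effects were set against the change with age in room air, on the hypothesis that P14 hyperoxia lungs are shifted towards the P29 room-air state and P29 hyperoxia lungs towards the P14 room-air state. Across 14989 genes the covariance was 0.0767 at P14 (r = 0.254) and -0.163 at P29 (r = -0.461), and 100 simulations of unchanged groups with the same shared room-air arrays gave means of 0.00813 (0.00762 to 0.00915) and -0.00811 (-0.00891 to -0.00763). The excesses of 0.0686 and -0.155 have the signs that both shifts would give. The simulated noise was independent for each gene, so a deviation of a room-air group common to many genes would give the same signs. The excesses therefore cannot tell the shifts from such a deviation. Room-air groups split in 2 parts would keep fewer than 2 arrays in each, so part of these correlations may come from shared controls. Only the simulated share of independent noise is removed from the excesses. The room-air age change also carries the difference in sex pattern between its arrays.

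The 6 hyperoxia arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. With limma the split by age called 4063 genes and the highest of the other splits 0, and at an unadjusted p under 0.05 the numbers were 5719 for the split by age and 252 to 581 for the others. As large a result came from 1 split, the real one. Every other split puts arrays of both ages in both groups, so the age difference adds to its spread and lowers its calls. The gap between the splits therefore does not measure chance.

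P29 hyperoxia replicate 3 held Xist at 11.94 together with a mean of 7.71 over 3 Y-linked genes, where the other arrays were high in one of these signals and low in the other. The labels name no sex, and the array stayed in its group.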
